A study of Mus musculus with 4 samples.

How the data were processed

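H3K9me3 was profiled by CUT&Tag in 4 mouse libraries, 1 per group: NTD_brain, control_brain, FA0_mESC and FA4_mESC. Per the labels' protocols, cells or tissues were fixed with formaldehyde, bound to beads, permeabilised and incubated with the antibody and a protein A-transposase, and the tagmented DNA was amplified. The labels' protocol names 1 antibody, while the catalogue number in the sample labels goes up by 1 from sample to sample, which reads like a filled spreadsheet column. How many embryos or cultures went into a library is not given in the sources used here. Per the submitters' processing notes, reads were aligned with BWA to mm10. The BWA version, the peak caller, its settings and any control library are not given in the sources used here.

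The authors deposited 1 annotated peak list per library, so peaks were called per sample. Per the file headers, each peak has a position, a width, a pileup (a fragment coverage signal), a fold enrichment (a ratio over background), a −log10 p-value and a −log10 q-value, and an assigned gene with the distance to its transcription start site (TSS). These deposited scores are the authors' own and were used to describe, rank and filter peaks within a list. Pileups at shared peaks, and backgrounds computed from the folds, were also compared between lists, without scaling for depth. Common cuts on pileup or fold were applied to both lists of a contrast. The deposited fold equals (pileup + 1) / (background + 1), from which the background of each peak was computed. A Poisson upper tail on the pileup with that background matched the deposited −log10 p-value of each peak checked, with a largest difference of 4.19e-05. This check covered every listed peak except 1 of FA4_mESC, whose tail was too small to compute. Backgrounds lay on steps of 0.0303 fragments in NTD_brain, 0.0296 in control_brain, 0.0223 in FA0_mESC and 0.0224 in FA4_mESC. Within a tolerance of 0.02 in half-steps, 100% of the values in both brain lists, 99.9% in FA0_mESC and 96.7% in FA4_mESC were on such steps, as a local window with few fragments gives. The lowest background of FA4_mESC, 0.0697 at 102 peaks, lay off the steps. The lowest of FA0_mESC was 0.0447, and those of NTD_brain and control_brain were 0.0908 and 0.0889. Where the caller takes the larger of a genome-wide and a local background, each of these bounds the genome-wide background of its library from above.

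Total reads per library are not given in the sources used here, so depth is known only through pileups and backgrounds. The lists held classes in or near genes and 0 intergenic peaks, and peak names ran up to 1958, 865, 3084 and 4804, so the listed peaks were 62.7%, 62.7%, 65.4% and 64.0% of the highest number. Peaks outside these lists were not analysed here, and every share is a share of listed peaks. H3K9me3 over gene-poor sequence, where the mark is abundant, is thus largely outside the data. How many of the listed peaks lie in repeats was not examined.

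Gene names, synonyms, biotypes and lengths came from the RefSeq gene table for GRCm38.p6. Its symbols matched 953 of 961 symbols of the NTD_brain list, 443 of 453 of control_brain, 1532 of 1553 of FA0_mESC and 2171 of 2196 of FA4_mESC. Peaks whose gene had no symbol made up 14.9%, 13.5%, 14.7% and 15.2% of the lists. All matched genes lay on the chromosome given by that table, but, within 5 kb, 7.63%, 6.32%, 7.77% and 7.44% of the peaks had their gene at its GRCm38 position. The coordinates are therefore printed as the files give them, with the build in doubt, and none was taken from the table.

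Covered length was the summed length of merged peaks. Peaks were shared where they overlapped by at least 1 bp. Shared numbers were set beside 100 random placements of the other library's peaks on the same chromosomes, and beside 100 placements within each peak's own listed transcript and 3 kb around it. Shares have Wilson 95% intervals and ratios of counts have exact conditional (Clopper-Pearson) 95% intervals. CUT&Tag fragments are amplified by PCR, and the intervals cover counting error only. TSS-proximal peaks are those the authors annotated to a promoter (within 2 kb) or a 5' UTR. A gene was counted as listed where the authors' annotation assigned it at least 1 peak. The annotation class of a peak need not belong to its assigned gene, and the assignments were not checked.

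The 23 gene lists were fixed before the data were examined: folate and one-carbon metabolism, neural tube closure, H3K9 methylation and heterochromatin, adenine methylation, zinc finger family, protocadherin clusters, olfactory receptors, vomeronasal receptors, Hox clusters, histone genes, predicted Gm genes, X-linked multicopy, imprinted, pluripotency, 2-cell-like, germline, neural progenitor, neuron, long neuronal adhesion and synaptic, mesenchyme and neural crest, blood and endothelium, endoderm and trophoblast, and housekeeping genes. For each list the number of protein-coding members with a peak was ranked among 10000 random lists of the same size, matched on gene length decile, drawn from 21896 protein-coding genes (seed 20). A list counted as outside the random range above percentile 97.5 or below percentile 2.5. This describes the libraries and is no test across samples. The predicted Gm list was given no percentile, because 6.09% of its matched members were protein-coding and most such genes carry no symbol in the files. It had 6 protein-coding members with a peak in NTD_brain, 3 in control_brain, 6 in FA0_mESC and 6 in FA4_mESC. The zinc finger list was drawn by symbol and holds genes without a KRAB domain.

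The named genes follow a rule fixed before the data were examined. Per contrast they are the 10 genes with the highest-fold peak that overlaps none of the other library, in each direction, the 5 with the highest-fold shared peak in the control library, the 5 with the most peaks in 1 library and none in the other, up to 4 members per list, the 10 genes with the most peaks in each same-direction overlap, and Alkbh1. Some genes that the rule takes are not reported here. Ties were broken by symbol, so among genes with equal peak numbers the named ones are the first in the alphabet. Further list members, and the regions in the closing part, were named after their values were seen.

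Alternatives fixed before the data were examined were a stricter threshold (fold above the median of both lists), equal peak numbers, autosomes and X only, peaks within 3000 bp joined, reciprocal overlap of 50%, overlap within 1000 bp, weighting by width, peaks within 10000 bp of the TSS and at least 2 peaks per gene. Minimum pileups of 3 and 8, gene length in 50 bins and placement within genes were chosen after seeing the data. The computations were tested on simulated data. Of 200 peaks planted in a second list, 200 were recovered on the NTD_brain list and 200 on the FA0_mESC list, with 0 others called. Planted peaks were shifted by less than the narrowest peak width and the other peaks were put on no real chromosome. No other outcome was possible, so this checks the code only. Among 200 random lists of 40 of the 21896 genes, 2.5% came out above the random range with no change planted in NTD_brain, 2.5% in control_brain, 3.5% in FA0_mESC and 3% in FA4_mESC. With 3-fold more peaks planted, 64% did in NTD_brain, 28% in control_brain, 81% in FA0_mESC and 93.5% in FA4_mESC. The simulated genes were drawn at the rates of the length deciles, so these simulations cannot show a length bias within deciles. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.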

Results

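The data consist of 4 mouse CUT&Tag libraries for trimethylation of lysine 9 on histone H3 (H3K9me3), a mark of repressed chromatin, with 1 library in each of 4 groups. CUT&Tag directs a transposase to antibody-bound chromatin, so that the sequenced fragments pile up where the mark lies. A pair of libraries came from embryonic brain. NTD_brain came from embryos with a neural tube defect, examined at E9.5 to E10.5, whose mothers had a low-folate diet and an intraperitoneal injection of 1.5 mg/kg MTX, a folate antagonist, at gestational day 7.5. The control_brain library came from embryos of the group given normal saline, whose diet is not given in the sources used here. The other pair came from Sv129 mouse embryonic stem cells (mESCs), cultured without folate (FA0_mESC) or with 4 mg/L folate (FA4_mESC). Each library is represented by its authors' annotated peak list. With 1 library per group no difference has a replicate check, no test was made across samples, and the intervals below cover counting error only.

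The lists held 1228 peaks for NTD_brain, 542 for control_brain, 2017 for FA0_mESC and 3075 for FA4_mESC. Most peaks rested on few fragments. The median pileup, the number of overlapping fragments at the summit, was 5 in NTD_brain and in control_brain, 3 in FA0_mESC and 4 in FA4_mESC, and the highest was 175, 169, 283 and 354 in the same order. The lowest pileup listed was 3 in both brain libraries and in FA4_mESC, and 2 in FA0_mESC, where 479 peaks had that value. The median peak width was 383 bp in NTD_brain, 385.5 bp in control_brain, 238 bp in FA0_mESC and 276 bp in FA4_mESC. Coordinates are printed as the files give them. The labels name the build mm10, but most of the listed genes do not lie at their GRCm38 positions, so the build of the printed coordinates is in doubt.

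The comparison of NTD_brain with control_brain asks which genes carried H3K9me3 peaks in brains with a neural tube defect after low folate and MTX, and in brains of the saline group. The peaks lay mostly at different genes. Pag1, Cdk8, Ablim1 and Src had strong peaks in NTD_brain alone, Egfem1, Notch3 and Cit in control_brain alone, and the Hedgehog pathway gene Smo in both. The Smo peak lay on a local background well above the library medians. The NTD_brain list was the longer one, with 2.27 times as many peaks (exact 95% interval 2.05 to 2.51), covering 484.7 kb against 214.2 kb. It assigned a peak to 1139 genes against 524 in control_brain. Of these genes 96 were common to both, 1043 were listed in NTD_brain alone and 428 in control_brain alone. With equal peak numbers the last 2 counts were 469 and 473. The excess shrank as the minimum pileup rose. The ratio was 2.01 (1.76 to 2.30) at a pileup of at least 5 and 1.58 (1.36 to 1.85) at a pileup of at least 6. At a pileup of at least 8 the libraries had 156 and 141 peaks, a ratio of 1.11 (0.875 to 1.40).

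The genes with the strongest peaks found in NTD_brain alone, by the authors' fold enrichment over local background, were Pag1, Cdk8, Ablim1, Tubd1, Loxl3, Isoc2a, Src, Myo16, Dab2ip and Atrnl1. All 10 peaks were intronic. The peak of Pag1, a membrane adaptor that binds the kinase Csk, lay in intron 1 of 8 (chromosome 3, 9867828 to 9868274) with a pileup of 35 and a fold of 17.0. The peak of Cdk8, the kinase of the Mediator complex, lay in intron 2 of 11 (chromosome 5, 146197829 to 146198177) with a pileup of 33 and a fold of 14.8. The actin-binding gene Ablim1 had a peak in intron 6 of 25 (chromosome 19, 57101647 to 57102023) with a pileup of 27 and a fold of 14.4, and the kinase gene Src had one in intron 2 of 13 (chromosome 2, 157287337 to 157287719) with a pileup of 16 and a fold of 11.0. For control_brain the corresponding genes included Egfem1, Coro2b, Col6a6, Rps6kc1, Notch3, Col26a1, Pex6, Cit and 1 gene without a symbol. The peak of Pex6, a peroxisome biogenesis gene, was exonic and those of the others named were intronic. Egfem1 had the strongest of them, in intron 4 of 5 (chromosome 3, 29381504 to 29381947), with a pileup of 35 and a fold of 17.7. The peak of Notch3, a Notch receptor gene, lay in intron 2 of 32 (chromosome 17, 32377993 to 32378308) with a pileup of 15 and a fold of 11.1, and that of Cit, which encodes citron kinase, a protein of cytokinesis, in intron 6 of 45 (chromosome 5, 116015633 to 116016040) with a pileup of 14 and a fold of 10.6. Coro2b and Col26a1 each also had 1 peak elsewhere in the gene in NTD_brain.

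Several genes held more than 1 peak in 1 brain library and none in the other. In NTD_brain these were led by Nos1, the neuronal nitric oxide synthase gene, and Rbfox1, a neuronal splicing regulator, with 4 peaks each. Ablim1, the transcription factor gene Cux2 and the growth factor receptor gene Fgfr2 followed with 3 each. The Fgfr2 peaks are spread from 129871155 to 131932840 on chromosome 7, a much longer stretch than the gene usually spans, so their assignment to Fgfr2 by the files is in doubt. In control_brain the highest number was 2, in Ephb1, Galnt7, Npsr1, Ntm and 1 gene without a symbol. Apart from the Ablim1 peak above and an Npsr1 peak with a pileup of 13, the peaks of these genes had pileups of 3 to 7.

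The brain libraries had few peaks in common. An overlap of at least 1 bp was found for 21 peaks, which is 1.71% of the NTD_brain peaks (Wilson 95% interval 1.12 to 2.60) and 3.87% of the control_brain peaks (2.55 to 5.85). Random placement of the control_brain peaks on their chromosomes gave 0.29 shared peaks on average (range 0 to 2 over 100 placements), and placement within their own genes gave 1.47 (range 0 to 5). The shared peaks with the highest fold in control_brain belonged to Gm21836, Smo, Sfi1, Slc25a47 and Lypd6. That of Smo, the transmembrane transducer of Hedgehog signalling, lay in intron 1 of 11 (chromosome 6, 29747913 to 29748679) and had a pileup of 76 in control_brain and 69 in NTD_brain. That of Sfi1, a centrosome gene, had 25 and 30. The local background at Smo was high, 4.18 in control_brain and 4.30 in NTD_brain, against library medians of 0.178 and 0.182. At Sfi1 it was 1.21 and 1.42. Strong peaks of 1 library alone also had backgrounds above the median, such as 1.12 at Pag1 in NTD_brain. Repeat content and mappability were not checked. At the promoter of Gm21836 the pileup was 49 in control_brain and 15 in NTD_brain, and at Lypd6 13 and 4. Over the 21 shared peaks the pileup was higher in NTD_brain at 9, lower at 11 and equal at 1, with a median ratio of 0.908. The genes in common were more numerous than for gene lists drawn independently within bins of gene length, 86 protein-coding genes against 42.3.

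**Figure D1:**
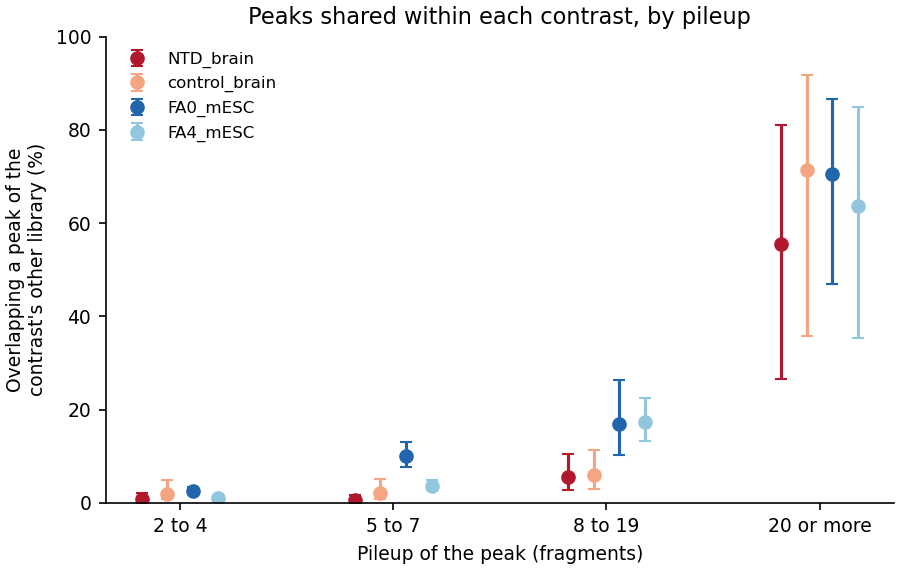
Share of each library's peaks that overlap a peak of the other library of its contrast (vertical axis, percent), by the pileup of the peak in fragments (horizontal axis). Points are the 4 libraries and bars are Wilson 95% intervals, which cover counting error only. Of the peaks with a pileup of 20 or more, 5 of 9 in NTD_brain, 5 of 7 in control_brain, 12 of 17 in FA0_mESC and 7 of 11 in FA4_mESC were shared. In each mESC library these peaks included 3 of the mitochondrial genome.

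Genes of folate and one-carbon metabolism had peaks at 3 of 38 members in NTD_brain and 2 in control_brain. Aldh1l1, a folate-oxidising enzyme gene, had a peak in both, with pileups of 8 and 7 at different places in the gene. Mthfd1l and Mthfd2, which encode mitochondrial folate enzymes, had a peak in NTD_brain alone (pileups 5 and 6), and Ftcd in control_brain alone (pileup 4). Neither count left the range of length-matched random lists (percentiles 84.7 and 90.5). Of 64 genes of the neural tube closure list, Sall4 (promoter, pileup 9) and Ptk7 (intron, pileup 3) had a peak in NTD_brain alone and Vasp (promoter, pileup 9) in control_brain alone, at percentiles of 15.1 and 30.5. The long neuronal adhesion and synaptic genes had 8 of 29 members with a peak in NTD_brain and 6 in control_brain. Those in both were Cdh13, Cdh18, Lrp1b, Magi2 and Nrg1. Gpc6, Lsamp and Opcml had a peak in NTD_brain alone, and Ntm in control_brain alone. The control_brain count lay above the random range (percentile 99.0), but not when length was matched in 50 bins instead of 10 (percentile 87.0).

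For the machinery of H3K9 methylation and heterochromatin, 2 of 35 genes had a peak in NTD_brain, the DNA methyltransferase gene Dnmt3a and the repressor gene Zfp568, and none had one in control_brain. The zinc finger family list, which holds KRAB repressors and other Zfp genes, had 16 of 429 members with a peak in NTD_brain and 4 in control_brain, at percentiles of 43.8 and 7.60. Zfp827 was the 1 gene in both, Zfp536 had 3 peaks in NTD_brain, Zfp277 and Zfp36l1 had 1 there, and Zfp131 had 1 in control_brain. The imprinted genes Rasgrf1 and Sgce, the germline genes Mov10l1 and Piwil1, the neuronal gene Rbfox3, Hoxd3 of the Hox clusters, Meox1 of the mesenchyme and neural crest list and Runx1 of the blood and endothelium list had a peak in NTD_brain alone. Esrrb of the pluripotency list had one in control_brain alone. The olfactory receptor genes Olfr56 in NTD_brain and Olfr1448 and Olfr71 in control_brain had a peak. No member of the neural progenitor, housekeeping, histone, protocadherin cluster, vomeronasal receptor, X-linked multicopy, 2-cell-like or endoderm and trophoblast lists had a peak in either brain library. Of 22 lists, 0 lay above the random range in NTD_brain and 1 in control_brain, where chance gives 0.55. The vomeronasal receptors and the protocadherins lay below the random range in NTD_brain (percentiles 0.205 and 0.345). The random lists draw genes independently, which clustered genes are not, so this does not show a depletion.

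The comparison of FA0_mESC with FA4_mESC asks the same of stem cells grown without and with folate. Strong peaks lay at Chl1, Ctnna3 and Lama1 in FA0_mESC alone, at Hivep1, Nectin2 and Dgki in FA4_mESC alone, and at the promoter of Gm21836 in both. The Gm21836 peak lay on a local background well above the library medians. Of the genes of folate and one-carbon metabolism, 8 had a peak in FA0_mESC and 3 in FA4_mESC. Here the folate-free library had the shorter list, with 0.656 times as many peaks (0.620 to 0.694), covering 530.6 kb against 911.9 kb. The direction was thus opposite to that in the brain. FA0_mESC assigned a peak to 1837 genes and FA4_mESC to 2644. Both lists held 486 genes, with 1351 in FA0_mESC alone and 2158 in FA4_mESC alone. With equal peak numbers the last 2 counts were 1481 and 1477. The deficit was larger at a pileup of at least 8 and was not detectable among the few strongest peaks. The ratio was 0.50 (0.470 to 0.532) at a pileup of at least 3 and 0.377 (0.297 to 0.477) at a pileup of at least 8, while at a pileup of at least 15, with 23 and 28 peaks, it was 0.821 (0.452 to 1.48). At a pileup of at least 20, with 17 peaks in FA0_mESC and 11 in FA4_mESC, it was 1.55 (0.683 to 3.65). Among these were 3 peaks of the mitochondrial genome, which carries no histones, in each library. Peaks at Gm21836, Gm10800 and Sfi1, on local backgrounds well above the library medians, were also among them in both.

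**Figure D2:**
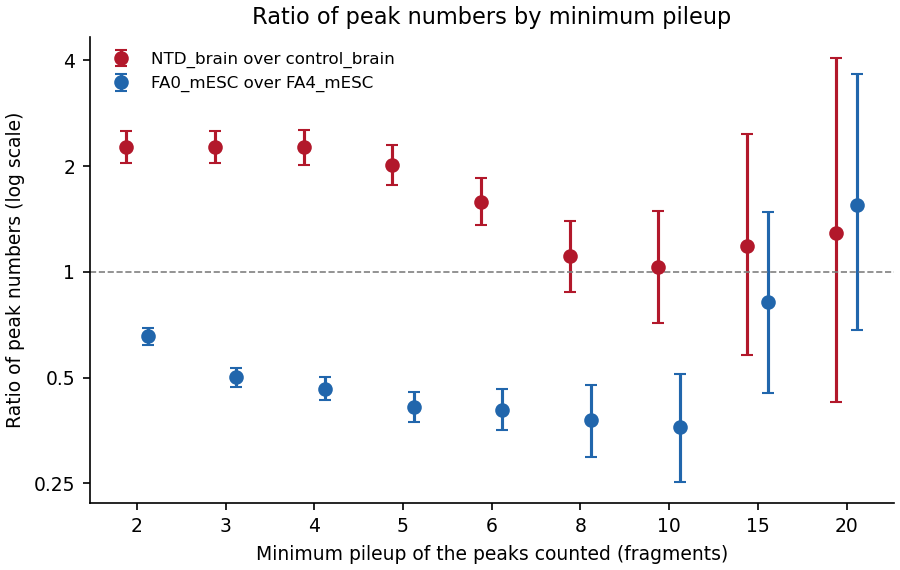
Ratio of peak numbers, NTD_brain over control_brain and FA0_mESC over FA4_mESC (vertical axis, log scale), among peaks with at least the pileup on the horizontal axis, in fragments. Bars are exact 95% intervals of the ratio of 2 counts and the dashed line marks equal numbers. The brain ratio goes from 2.27 to 1.11 at a pileup of at least 8, and the mESC ratio from 0.656 to 0.377.

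The strongest peaks found in FA0_mESC alone were in Chl1, Ctnna3, Lama1, Drc1, Ntm, Htr4, Slco3a1, Lrrk1, Rai14 and 1 gene without a symbol, all in introns. The peak of Chl1, a neural cell adhesion gene, lay in intron 3 of 26 (chromosome 6, 103626041 to 103626233) with a pileup of 26 and a fold of 16.7. The peak of Ctnna3, an alpha-catenin gene, lay in intron 9 of 17 (chromosome 10, 64120192 to 64120418) with a pileup of 22 and a fold of 15.4, and that of Lama1, a laminin chain gene, in intron 5 of 62 (chromosome 17, 68048360 to 68048601) with a pileup of 19 and a fold of 13.4. Chl1, Ctnna3, Drc1, Ntm, Lrrk1 and Rai14 also had 1 to 3 peaks elsewhere in the gene in FA4_mESC. The corresponding genes of FA4_mESC included Hivep1, Nectin2, Myo18a, Anxa6, Dgki, Rnf150, Insyn2b, Scrn1 and 1 gene without a symbol, and none of them had a peak in FA0_mESC. Hivep1, a zinc finger transcription factor gene, had the strongest (intron 2 of 8, chromosome 13, 42248397 to 42248822, pileup 20, fold 13.3). Those of Dgki, Rnf150 and Scrn1 lay at promoters, with pileups of 11 to 14 and folds of 9.29 to 9.57.

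Genes with several peaks in 1 mESC library and none in the other were Csmd3, Etv6, Gli2, Immp2l and Ldlrad4 in FA0_mESC, with 3 peaks each. Gli2 encodes a transcription factor of the Hedgehog pathway, and its strongest peak lay in an intron with a pileup of 8 and a fold of 6.80. The 3 peaks of Csmd3 all had a pileup of 2. In FA4_mESC the genes were Cald1, Lipc, Magi2, Nedd4l and Negr1 with 4 peaks each. The peaks of Cald1, the caldesmon gene, had pileups of 5 to 9, and those of Lipc, the hepatic lipase gene, 3 to 10.

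The mESC libraries, with their longer lists, had few peaks in common too. An overlap was found for 110 FA0_mESC peaks, or 5.45% (4.54 to 6.53), and 109 FA4_mESC peaks, or 3.54% (2.95 to 4.26). Random placement of the FA4_mESC peaks gave 2.75 shared peaks on average (range 0 to 7), and placement within their genes 8.74 (range 3 to 16). Of the shared FA0_mESC peaks 61.8% were TSS-proximal, meaning at a promoter or in a 5' UTR, against 19.8% of the others. The shared peaks with the highest fold in FA4_mESC were at Gm21836 (pileup 354 in FA4_mESC and 283 in FA0_mESC), Cldn34d (22 and 25), Dop1b (19 and 25), Ppp1r9a (17 and 36) and a gene without a symbol (15 and 36). Over the 109 shared FA4_mESC peaks the pileup was higher in FA4_mESC at 62, lower at 33 and equal at 14, with a median ratio of 1.22. The lists had 443 protein-coding genes in common, against 314.9 for lists drawn independently within bins of gene length.

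Folate and one-carbon metabolism genes had peaks at 8 of 38 members in FA0_mESC and at 3 in FA4_mESC, with no member in both. The FA0_mESC members were Mthfd1l (2 peaks), Aldh1l2, Folr2, Gldc, Gnmt, Mthfd2, Mtr and Mtrr. They include the methionine synthase gene Mtr, its reductase gene Mtrr and the glycine cleavage gene Gldc. The strongest peak of each of the 8 genes was annotated as intron or 3' UTR, a class that need not belong to the assigned gene. The Gnmt peak, of class 3' UTR, lay at -7658 bp from the Gnmt TSS, upstream of that gene. The FA4_mESC members were Gart, a purine synthesis gene, Slc25a32, the mitochondrial folate carrier gene, and Cth. Random lists of the same lengths had 2.48 members with a peak on average in FA0_mESC, which put the list at percentile 99.9, and 3.54 in FA4_mESC, percentile 40.7. The strongest FA0_mESC peak of each gene had a pileup of 2 to 5. At a pileup of at least 3 the list had 6 members in FA0_mESC and 3 in FA4_mESC, while at a fold above the median of both lists it had 2 in each and at a pileup of at least 8 it had 0 in each. With peaks within 10000 bp of the TSS it had 4 and 3, and no longer lay above the random range in FA0_mESC.

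The neural tube closure list had 11 of 64 members with a peak in FA0_mESC (random mean 6.21), at the edge of the random range but not above it (percentile 97.5), and 9 in FA4_mESC (percentile 53.8). Arid1b, a chromatin remodelling gene, had 2 peaks in each. Gli2 with 3 peaks and the actin regulator gene Enah with 2 were listed in FA0_mESC alone, and Gli3 and Tcof1 with 2 peaks each in FA4_mESC alone. Of the long neuronal genes 15 of 29 had a peak in FA0_mESC and 21 in FA4_mESC, 11 of them in both, among them Cdh13, Ctnna3, Lsamp and Macrod2. Magi2 and Csmd1 had peaks in FA4_mESC alone, and Csmd3 in FA0_mESC alone. Both counts lay above the random range (percentiles 99.9 and 99.995), and with 50 length bins FA4_mESC alone did (91.7 and 98.4). Housekeeping genes had a peak at 4 of 18 members in FA4_mESC (random mean 0.902, percentile 99.3) and 1 in FA0_mESC (percentile 67.6). They were Hsp90ab1, Ppia, Rpl13a and Polr2a, each at a promoter or in a 5' UTR, and Polr2a, which encodes the largest subunit of RNA polymerase II, was the 1 gene in both. Neither the housekeeping nor the long neuronal list lay above the random range in either mESC library at a pileup of at least 8.

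**Figure D3:**
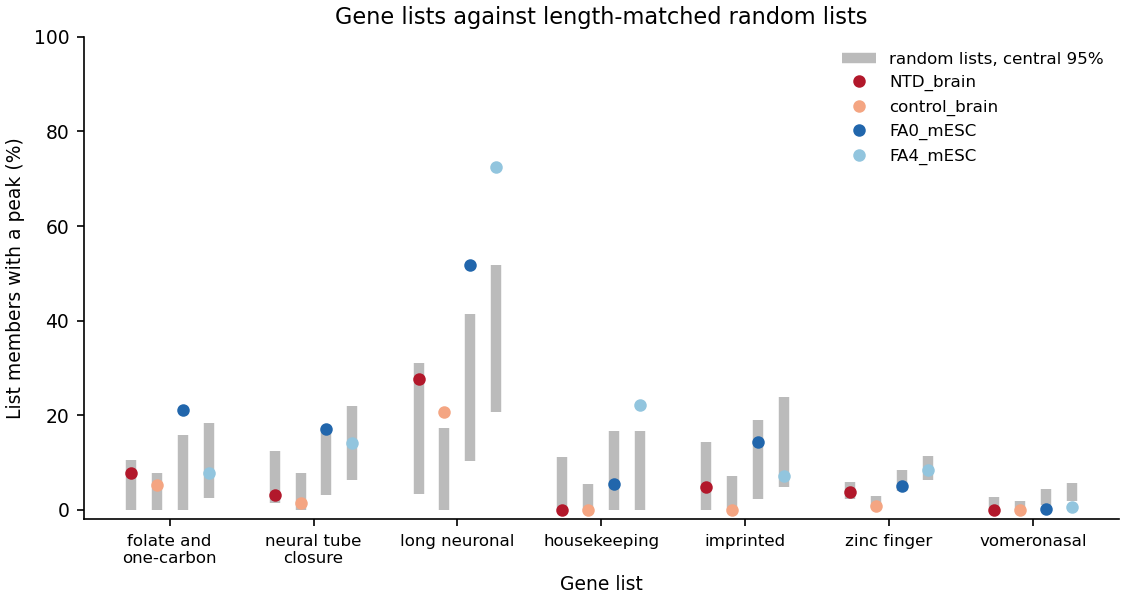
Percent of the members of 7 gene lists that have a peak (points, vertical axis) in each of the 4 libraries, with the central 95% of 10000 random lists matched on gene length decile (grey bars). The folate and one-carbon list has 21.1% of its members with a peak in FA0_mESC, against 7.89% in FA4_mESC, and the housekeeping list has 22.2% in FA4_mESC.

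Among genes of H3K9 methylation and heterochromatin, 5 of 35 had a peak in FA0_mESC and 4 in FA4_mESC, none in both. The heterochromatin protein gene Cbx5 had 2 peaks in FA0_mESC, where Atf7ip and Hells each had 1 at the promoter, while the maintenance DNA methyltransferase gene Dnmt1 had 1 in FA4_mESC. The percentiles were 80.9 and 33.4. The imprinted genes had 6 of 42 members with a peak in FA0_mESC, including Gnas with 2 peaks, Ddc and Impact, and 3 in FA4_mESC, including Trappc9 with 4 peaks. The strongest Gnas peak, of a downstream class, lay at -3856 bp from the Gnas TSS, upstream of it. Pluripotency genes had 3 of 23 in FA0_mESC (Nanog, Tet1 and Tet2) and 2 in FA4_mESC (Tbx3 and Tfcp2l1). For germline genes Mov10l1, Piwil1 and Tdrd9 were listed in FA0_mESC and Piwil4 in FA4_mESC. Of the neural progenitor genes, Dbx1, Nkx6-1 and Olig2 had a peak in FA0_mESC and Vim in FA4_mESC. The Dbx1 peak, of class 3' UTR, lay 28687 bp from the Dbx1 TSS, so its assignment is in doubt. Of the neuronal genes, Nefl and Stmn2 had a peak in FA0_mESC alone, Lhx3 and Map2 in FA4_mESC alone, and Rbfox3 in both. The zinc finger family had 22 of 429 members with a peak in FA0_mESC (such as Zfp143) and 36 in FA4_mESC (such as Zfp180, Zfp189 and Zfp710, the last with 2 peaks). Zfp367 was the 1 member in both, and both counts lay within the random range. Hoxa13 had a peak in both libraries, Hoxa7 in FA0_mESC and Hoxb3 in FA4_mESC alone. The histone genes H3c7 and H4c11, Pdgfra of the mesenchyme list and Runx1 of the blood list had a peak in FA4_mESC alone. No member of the 2-cell-like, endoderm and trophoblast or X-linked multicopy lists had one in either library.

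The clustered receptor families lay below their random range in both mESC libraries. Olfactory receptors had a peak at 5 of 1110 genes in each (random means 11.1 and 13.5), among them Olfr1277 and Olfr1364 in FA4_mESC and Olfr1348 and Olfr203 in FA0_mESC. Of the vomeronasal receptors, Vmn1r198 had a peak in FA0_mESC and Vmn1r35 and Vmn2r102 in FA4_mESC, 1 and 2 of 353 members. Clustered protocadherins had a peak at 0 of 57 members in FA0_mESC and at 1, Pcdhb22, in FA4_mESC, against random means of 7.60 and 10.8. The random lists draw genes independently, which genes of a cluster are not, and each peak is assigned to 1 gene. The low counts of these families therefore do not show a depletion of H3K9me3. Of 22 lists, 2 lay above the random range and 3 below it in each mESC library, where chance gives 0.55 on each side.

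The share of TSS-proximal peaks differed between the sample types. Over all listed peaks its intervals overlapped within each contrast, and among peaks with a pileup of at least 8 they were apart within the mESC contrast. TSS-proximal peaks made up 11.9% (10.2 to 13.8) of the NTD_brain list and 11.1% (8.70 to 14.0) of the control_brain list. They made up 22.1% (20.4 to 24.0) of FA0_mESC and 21.7% (20.3 to 23.2) of FA4_mESC. Introns held 76.1%, 75.5%, 67.8% and 70.0% of the peaks in the same order. Peaks in 3' UTRs took 2.58% (1.97 to 3.37) of FA0_mESC and 1.17% (0.847 to 1.62) of FA4_mESC. At a pileup of at least 8 the TSS-proximal share was 46.0% (40.1 to 52.1) in FA4_mESC and 21% (14.2 to 30.0) in FA0_mESC.

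**Figure D4:**
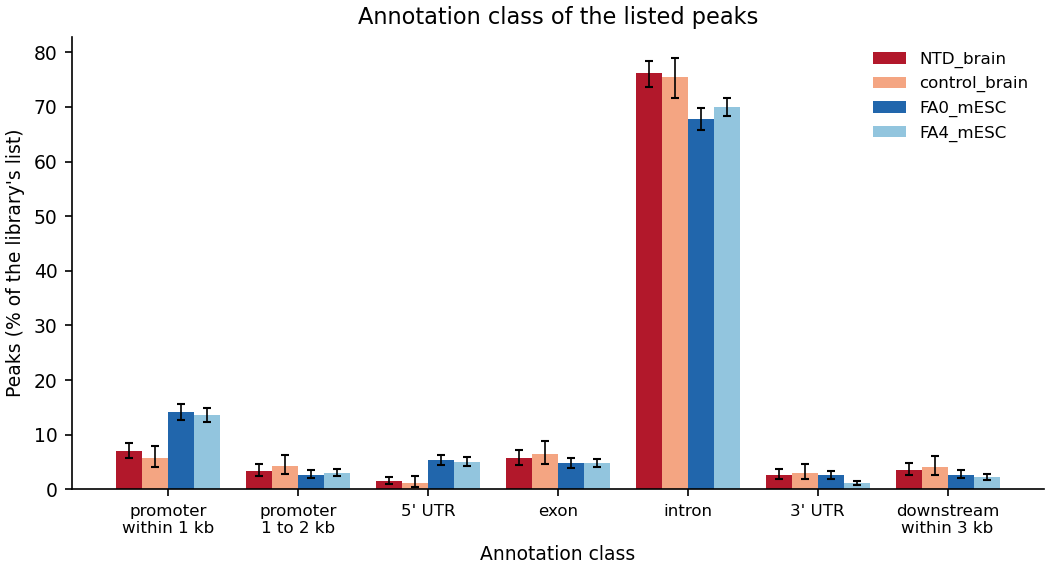
Percent of each library's listed peaks (vertical axis) in each annotation class given by the authors' files (horizontal axis). Bars are the 4 libraries and error bars are Wilson 95% intervals, which cover counting error only. Promoters within 1 kb hold 7.0% and 5.72% of the brain lists and 14.1% and 13.6% of the mESC lists.

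The share of peaks per chromosome did not separate the brain libraries on any chromosome. X held 12 of the 1228 NTD_brain peaks and 1 of the 542 control_brain peaks, or 0.977% and 0.185%. In mESCs the intervals were apart on chromosome 1, with 8.38% of FA0_mESC peaks (7.25 to 9.67) and 5.76% of FA4_mESC peaks (4.99 to 6.64), and on chromosome 8, with 5.85% (4.91 to 6.96) and 8.16% (7.25 to 9.18). All chromosomes were compared without correction for their number. Chromosome copy number was not measured, so a difference in H3K9me3 is not shown. X held 2.08% and 1.33% of the mESC peaks.

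The 2 contrasts were then set side by side, since both lower the folate supply and share no library. Of protein-coding genes, 85 were listed in NTD_brain alone within the brain contrast and in FA0_mESC alone within the mESC contrast, against 73.5 expected for independent lists with matched gene lengths. They were led by Etv6, a transcriptional repressor gene (2 peaks in NTD_brain and 3 in FA0_mESC), Grin2b, an NMDA receptor subunit gene (2 and 2), Pcsk6 and Slc25a13 (1 and 3 each) and Camkmt (2 and 1), followed by Dennd1a, Mthfd1l, Pam and Rnf220 (1 and 2 each) and 1110051M20Rik (1 and 1). For control_brain and FA4_mESC the overlap was 68 genes against 47.9. It included Sh3pxd2a (1 and 3), Galnt7 (2 and 1), and Barhl1, Cdh22, Col16a1, Dgki, Dip2b, Egfem1, Epb41l3 and Nfatc1 (1 and 2 each). The opposite pairings gave ratios of the same order, 159 genes against 123.2 for NTD_brain with FA4_mESC and 36 against 28.7 for control_brain with FA0_mESC. The excess of the same-direction overlaps over their expectation, 1.16-fold and 1.42-fold, was thus not set apart from that of the opposite pairings, 1.29-fold and 1.26-fold. Within 10000 bp of the TSS the ratios were 0.959 (0.479 to 1.72) for NTD_brain with FA0_mESC and 1.47 (0.703 to 2.70) for control_brain with FA4_mESC, whose interval over all peaks, 1.10 to 1.80, excluded 1. Overlapping peaks numbered 14 and 5 for the same-direction pairs, and 20 and 5 for the opposite pairings.

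The unperturbed libraries differ in cell type and in library together, so their comparison is context only. Control_brain and FA4_mESC shared 10 peaks, 1.85% (1.01 to 3.36) of the control_brain list, against 0.41 (range 0 to 2) for random placement and 1.69 (range 0 to 5) for placement within genes. Alkbh1, the AlkB-family demethylase gene named in the study's title, had no listed peak in any of the 4 libraries, and neither had the other members of the adenine methylation list of 9 genes.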

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

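All tests weighed here were chosen after the result was seen. Several results went in opposite directions in the brain contrast (NTD_brain against control_brain) and in the mESC contrast (FA0_mESC against FA4_mESC), and none of these differences was tested, since each group has 1 library. The ratio of peak numbers was 2.27 in the brain and 0.656 in mESCs, that of covered lengths 2.26 and 0.582, and that of genes with a peak 2.17 and 0.695. Zinc finger family members with a peak differed by 12 in the brain and by -14 in mESCs, and long neuronal adhesion and synaptic genes by 2 and -6. The zinc finger counts all lay within the random range, and the random means, 16.8 and 7.74 in the brain and 26.1 and 37.4 in mESCs, differ in the same directions, as list lengths do. So do the random means of the long neuronal list, 4.53 and 2.13 in the brain and 7.28 and 10.4 in mESCs. Pluripotency genes differed by -1 and 1, mesenchyme and neural crest genes by 1 and -1, and blood and endothelium genes by 1 and -1.

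The first pattern is the longer list of NTD_brain. An excess limited to peaks below a pileup of 8 goes with the ratio of 1.11 (0.875 to 1.40) at a pileup of at least 8. That interval includes 1 and excludes 2.27. The excess was not confined to the lowest pileups. The ratio was 2.01 (1.76 to 2.30) at a pileup of at least 5 and 1.58 (1.36 to 1.85) at 6. Above the median fold it was 1.68 (1.46 to 1.93). Whether NTD_brain was sequenced more deeply cannot be told apart from equal depth. The median pileup ratio over the 21 peaks called in both libraries was 0.908, with a bootstrap interval of 0.714 to 1.20 that spans 1. An effect of low folate and MTX on H3K9me3 stays open and untested, since each brain group is 1 library.

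The second pattern is the shorter list of FA0_mESC. At a pileup of at least 8 the ratio was 0.377 (0.297 to 0.477), further from 1 than over all peaks. At a pileup of at least 20 the interval included 1 (0.683 to 3.65). These cuts were not scaled for depth, and the same cut is stricter in a shallower library. They therefore cannot tell whether the deficit is limited to peaks near the threshold. A shallower FA0_mESC library is a candidate explanation. The lowest background of FA4_mESC was 1.56 times that of FA0_mESC, which orders their depths only if the caller takes the larger of a local and a genome-wide background and the value of FA4_mESC, shared by 102 peaks and off the steps of its local windows, is its genome-wide one. An effect of folate-free medium stays open and untested, because the medium and the library cannot be separated with 1 library each.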

How the results depend on the processing

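No paired analysis was possible because each group has 1 library, and for the same reason no library could be left out. Tests with a minimum pileup of 3 or 8 and with 50 gene length bins were chosen after the data were seen. Of 233 values under alternatives, 141 stayed within their interval or within 1.5 times the main count, and 92 moved. Part of the 141 could not move. The brain lists had 0 peaks on Y or the mitochondrial genome, so autosomes and X only left them as they were. A minimum pileup of 3 did the same to both brain lists and FA4_mESC, and equal peak numbers to the shorter list of each contrast. The number that stayed is therefore no measure of robustness. No ratio of peak numbers or covered lengths crossed 1 under these alternatives. The ratio of shared genes to expectation for NTD_brain with FA0_mESC, whose interval of 0.924 to 1.43 includes 1, went from 1.16 to 0.959 within 10000 bp of the TSS. For control_brain with FA4_mESC it went from 1.42 (1.10 to 1.80) to 1.47 (0.703 to 2.70), an interval that includes 1. With peaks within 3000 bp joined and with weighting by width, no value moved. With autosomes and X only none moved either, where only the mESC lists lost any peaks. Equal peak numbers fix the ratio of peak numbers, which was left out. The cause of the moved values was not tested, except that keeping fewer peaks of a library lowers its own number of genes with a peak by construction. Most peaks rest on few fragments, with a median pileup of 3 to 5, and the depth of the libraries is not known.

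With equal peak numbers, the ratio of covered lengths was 1.02 in the brain and 0.883 in mESCs. The shared share of NTD_brain peaks was 2.95%, of FA4_mESC peaks 4.76%, and of control_brain peaks with FA4_mESC 0.923%. The TSS-proximal share of FA4_mESC was 25%, above the 22.1% of FA0_mESC, while over all peaks it was below it. In the brain 51 genes were in both lists, 469 in NTD_brain alone and 473 in control_brain alone, so that the order of the last 2 turned. In mESCs 1481 were in FA0_mESC alone and 1477 in FA4_mESC alone, where the order turned too. Equal peak numbers bring the counts of genes in 1 library alone close together by construction, so these changes of order carry no weight. Of the gene lists, 1 of NTD_brain lay above the random range.

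Above the median fold, the ratios of peak numbers and covered lengths were both 1.68 in the brain, and 0.538 and 0.484 in mESCs. The shared share was 7.93% of FA0_mESC and 4.27% of FA4_mESC, and the TSS-proximal share 26.5% and 25.5%. Brain genes numbered 40 in both, 485 in NTD_brain alone and 279 in control_brain alone, and mESC genes 166 in both, 656 in FA0_mESC alone and 1319 in FA4_mESC alone. Lists above the random range numbered 1 in NTD_brain and 1 in FA4_mESC.

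At a pileup of at least 3, the mESC ratios were 0.50 for numbers and 0.447 for covered lengths, and 7.09% of FA0_mESC peaks were shared and 25.4% TSS-proximal. At a pileup of at least 8, the ratios were 1.11 and 1.13 in the brain, and 0.377 and 0.322 in mESCs. The shared share was 6.41% in NTD_brain, 7.09% in control_brain, 20% in FA0_mESC and 7.17% in FA4_mESC, and 46.0% of FA4_mESC peaks were TSS-proximal. X held 0% of control_brain, 1% of FA0_mESC and 0.755% of FA4_mESC peaks. Genes in both lists, in the first alone and in the other alone numbered 12, 140 and 125 in the brain, and 20, 75 and 235 in mESCs. Lists above the random range numbered 0 in control_brain, 0 in FA0_mESC and 0 in FA4_mESC.

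With reciprocal overlap of 50%, 4.02% of FA0_mESC and 2.63% of FA4_mESC peaks were shared, and within 1000 bp 6.74% and 4.39%. Within 10000 bp of the TSS, genes numbered 14 in both, 456 and 183 in the brain, and 128, 798 and 1201 in mESCs, and lists above the range 0 in control_brain, 0 in FA0_mESC and 1 in FA4_mESC. With at least 2 peaks per gene they numbered 4, 67 and 13 in the brain, and 33, 121 and 300 in mESCs, with 0 lists above the range in control_brain and 1 in FA4_mESC. With 50 length bins, 0 lists lay above the range in control_brain and 1, folate and one-carbon metabolism, in FA0_mESC.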

Other observations

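All tests in this part were chosen after the result was seen. A few regions were listed in every library. Merging the peaks of the 4 lists gave 6678 regions, of which 6507 came from 1 library, 162 from 2, 6 from 3 and 3 from all 4. The 3 were an intron of ENSMUSG00000117042 (chromosome 17, 13772087 to 13773391, pileups 175 in NTD_brain, 169 in control_brain, 18 in FA0_mESC and 14 in FA4_mESC), intron 1 of Smo (69, 76, 6 and 5) and the promoter of Gm21836 (15, 49, 283 and 354). The first 2 had their higher pileups in the brain lists and Gm21836 in the mESC lists. Those found in 3 lists were in or beside Sgpl1, Sfi1, Gm3411, Thada, Slc2a10 and ENSMUSG00000110388, and these regions were named after their values were seen.

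The mitochondrial genome, which carries no histones, was listed in both mESC libraries and in neither brain library. FA0_mESC had 2 peaks assigned to mt-Nd5 (pileups 47 and 43) and 1 to mt-Nd2 (38), and FA4_mESC had 1 assigned to mt-Nd5 (70) and 2 to mt-Nd1 (66 and 63). Gm10800, beside Gm10801 on chromosome 2, had the peak with the second highest pileup in both mESC lists, 123 in FA0_mESC and 103 in FA4_mESC. The local backgrounds there were 8.73 and 7.98. Sfi1 was among the 10 peaks with the highest pileup in all 4 lists.

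The share of TSS-proximal peaks was higher in the mESC lists than in the brain lists. Peaks within 2000 bp of the TSS were set beside random placement of the peaks in their own genes. The random share was 13.2% in FA4_mESC, 13.8% in FA0_mESC, 13.1% in NTD_brain and 13.8% in control_brain. These near-equal shares argue against shorter genes as the source of the difference. The observed shares were 31.2%, 33.5%, 19.4% and 17.9% in the same order, or 2.36, 2.42, 1.48 and 1.30 times the random ones. Placed peaks were not reassigned to a nearer TSS, which can raise these ratios in every library. Tagmentation of accessible promoters of active genes cannot be told apart from H3K9me3 there, because the housekeeping list stood at percentile 99.9 for TSS-proximal peaks in FA4_mESC and at 83.9 in FA0_mESC. The difference in cell type stays open and untested, since it goes with the library.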
